A study of Drosophila melanogaster with 60 samples.

How the data were processed

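RNA was taken from heads of Drosophila melanogaster, and per the labels' protocols the 3′ RNA-seq libraries were made by selecting poly(A) RNA after fragmentation. The 60 libraries fall into 24 groups of genotype and time, taken with their replicate numbers from the sample labels: 12 libraries each of conOE and OE (6 times, 2 courses) and 18 each of conRNAi and RNAi (6 times, 3 courses). The labels give no sex, and no statement of which libraries share flies. Per the submitters' processing notes, Bowtie and TopHat (versions not given in the sources used here) and the genome build dm3 were used. The counting tool, annotation, normalisation and filter are not given in the sources used here.

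Per the file headers the deposited tables hold 1 value per transcript and library, 8669 transcripts in the overexpression table and 8443 in the RNAi table. From the values, this deposited signal is a read count divided by a size factor of its library: in 59 of 60 libraries every value was a whole number of reads, within 0.05 reads, and in the remaining library 1 value was not. No listed value was 1 or lower. In every library the lowest listed value was at least 1 read, so each listed transcript had reads in all libraries of its table. Genes without reads in some library, such as genes silent in 1 genotype, are thus absent, and the counts of measured genes exclude them. The authors also deposited averages over replicates, which in the overexpression table equal the sum of 2 replicates divided by 3 and were not used. The deposited p-values and q-values of the authors' rhythm test, which the headers do not name, were counted at a q under 0.05 only to set beside the counts of rhythmic genes. Its deposited periods, phases and amplitudes were not used. The read totals recovered from the steps had medians of 3365606 (conOE), 2308046 (OE), 4750668 (conRNAi) and 2720848 (RNAi), so the libraries of labelled groups were shallower than their controls.

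Some listed transcripts, 325 in the overexpression table and 308 in the RNAi table, repeated the values of another. Other transcripts of the same gene had values of their own. For each gene the transcript with the highest mean was kept, which left 7648 and 7444 genes. This choice was made after the values were seen. Gene symbols came from a RefSeq gene table (assembly Release 6 plus ISO1 MT) through the CG numbers: 7378 and 7186 genes matched by locus tag, 218 and 207 by synonym, and 52 and 51 kept their listed name. That table is of another build than dm3 and was used for names and chromosome arms, with no coordinates. In 47 and 44 cases different genes shared 1 set of values, and the separate values of such genes, of near-identical copies (Amy-p and Amy-d, the Hsp70 genes) and of overlapping genes are uncertain. The 48 pairs of replicate libraries compared by a chi-square test on genes with 20 or more reads differed by more than sampling noise (chi-square per degree of freedom 3.66 to 32.1), so no pair looked like 1 library listed again. This does not show that replicate libraries came from separate flies, and libraries were counted as replicates from the labels.

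The genotype effect was fitted within each experiment by limma-trend 3.58.1 in R 4.3.3 on log2(value + 1), with time as a factor and Benjamini-Hochberg adjustment. Fold changes are on this scale, which understates the change of low genes. The planned filter, a mean of at least 1, removed no gene. A joint test of the genotype-by-time terms asked whether the difference depended on time. Rhythms were tested by a 24 h harmonic within each genotype, and the difference in rhythm by the terms of genotype with the harmonic. Genes passing in both experiments were compared with Fisher's exact test over 6987 shared genes. The tests, covariates, gene lists and the rule for named genes were fixed before the data were examined. A count model was planned for count tables and limma-trend for normalised values; the tables held normalised values, so limma-trend was used, and the planned DESeq2 alternative, which applied to counts only, was not run. The rule named cbt, 8 clock genes, the 10 largest increases and the 10 largest decreases with the same sign at 5 or more of 6 times, 2 to 4 members of lowest p per list, 5 genes per interaction or rhythm test and 5 per overlap class. Further list members and members of name families, among them Gk1, Pepck1, Gk2, DnaJ-1, inaD, sNPF-R, fit, Act57B, Dcr-2, v, nmo, brp, Taldo, Mtk and BomBc1, were named after their values were seen.

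The 27 lists covered core clock and kinases, clock output, sugar sensing, gluconeogenesis with glyceroneogenesis and cataplerosis, glycolysis, pentose phosphate, lipid synthesis, lipolysis, amylases and maltases, gut serine proteases, insulin and adipokinetic hormone, feeding neuropeptides, head fat body, sex-biased genes, photoreceptor, pan-neuronal, glia, muscle, cuticle, antimicrobial, heat shock and Turandot, mitochondrially encoded, ribosomal, detoxification, activin and JNK, activity-regulated and construct genes. The 26 lists with 3 or more measured genes in an experiment were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. With the preset correlation 11 lists passed in the overexpression experiment and 7 in the RNAi experiment, and with an estimated correlation 1 and 0. The cuticle pattern also takes the P450 reductase gene Cpr. The genes cbt, daw, kay and trpl stand in more than 1 list.

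The alternatives fixed with the tests were median-ratio rescaling, no filter and a mean of at least 10, pseudocounts of 0.1 and 5, each course and each time left out, the replicate number as a block, 1 value per course, and the course as a random block. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads, TMM scaling of the values, leaving out the libraries under 1000000 reads, all distinct transcripts, and a crossed block. On the recovered reads edgeR called 3474 genes in the overexpression experiment and 1913 in the RNAi experiment, 3025 and 1603 of them shared with limma. The limma tests of the genotype effect, the genotype-by-time terms, the rhythm difference and rhythms in the control libraries were checked on simulated data, and the list, family and overlap tests were not. For the genotype effect 68% of 1.5-fold and 93.3% of 2-fold genotype changes were recovered over the 7648 genes of the overexpression experiment, and 86% and 100% over the 7444 of the RNAi experiment. Far fewer genes were changed in the simulated data than were called in the real data. The simulated libraries also had no course differences, so recovery in the real data may differ. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures. Random draws other than the simulated data used the seed 11.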

Results

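Heads of Drosophila melanogaster were profiled by 3′ RNA-seq, a method that counts reads from the poly(A) end of each transcript, in 60 libraries from 2 experiments on cabut (cbt, CG4427). This gene encodes a zinc finger transcription factor that acts downstream of sugar sensing. In the overexpression experiment, flies with the Tim-gal4 driver alone (labelled conOE) were set against flies with the driver and a UAS-cbtFLAG transgene (labelled OE). In the RNAi experiment, flies with the driver and UAS-Dcr2 (labelled conRNAi) were set against flies with the driver and a UAS construct for RNAi against cbt (labelled RNAi), whose label lists no UAS-Dcr2. Tim-gal4 drives UAS transgenes in cells that express the clock gene timeless. Heads were collected at 6 Zeitgeber times (ZT, hours after lights on): 3, 7, 11, 15, 19 and 23. Each genotype of the overexpression experiment was followed in 2 replicate courses (12 libraries), and each genotype of the RNAi experiment in 3 courses (18 libraries). Reads recovered from the normalised values ranged from 468075 to 5512461 per library in the overexpression experiment and from 349019 to 13922764 in the RNAi experiment, with 4 and 3 libraries under 1000000. The labels do not say that the courses came from separate groups of flies, so p-values measure the spread between these libraries, which can be technical. The tables of the 2 experiments were normalised separately, and the tests of genes and gene lists were run within 1 experiment.

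The targeted gene went against its label in the overexpression experiment. The normalised read count of cbt was 284.9 ± 31.4 (SD, n = 12) in the conOE libraries and 95.4 ± 25.5 (SD, n = 12) in the libraries labelled OE, a log2 change of -1.61 (SE 0.121, limma adjusted p = 3.41e-11). The 12 libraries labelled OE lay between 54.74 and 140.3, all below the 12 conOE libraries at 232.6 to 354.8, and their mean was lower at 6 of 6 times. In the RNAi experiment cbt was at 317.7 ± 36.7 (SD, n = 18) in the conRNAi libraries and 308.2 ± 55.5 (SD, n = 18) in the libraries labelled RNAi, a log2 change of -0.06 that was smaller than the spread between libraries (SE 0.0678, adjusted p = 0.618). The sign of this small change turned without RNAi course 3 (0.01) and without ZT23 (0.015). Each table lists 1 cbt transcript (CG4427-RA). The labels do not give the 3′ end of the transgene's transcripts, so the cbt value checks the overexpression label only if those transcripts share the counted end. For these reasons the groups are called the libraries labelled OE and the libraries labelled RNAi throughout, and every direction given below is that of the labelled group against its labelled control.

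Among 4 measured genes of fly constructs and markers (cbt, Dcr-2, w and v), the eye pigment transporter gene w, a marker carried by many UAS insertions, was higher in both labelled groups. It rose from 16.5 ± 6.51 to 86.9 ± 13.3 (SD, n = 12 each) in the libraries labelled OE, a log2 change of 2.42 (SE 0.154, adjusted p = 1.36e-12), with no overlap between the ranges of 6.57 to 29.47 and 62.21 to 107.8. In the libraries labelled RNAi it rose from 35.0 ± 11.7 to 70.4 ± 20.3 (SD, n = 18 each), a log2 change of 0.996 (SE 0.119, adjusted p = 9.45e-09). Dcr-2 did not pass in either experiment, with log2 changes of -0.22 (adjusted p = 0.266) and -0.19 (adjusted p = 0.169), except in the RNAi experiment without RNAi course 3 (-0.28, adjusted p = 0.0277). The labels give UAS-Dcr2 to conRNAi and not to RNAi. Dcr-2 thus did not clearly bear out this difference in label, if that transgene's transcripts share the counted end. The pigment synthesis gene v was at 0.32 (adjusted p = 0.117) in the overexpression experiment, where it passed without conOE course 1 (0.58, adjusted p = 0.0137) and without OE course 1 (adjusted p = 0.013). It fell by 0.24 (adjusted p = 0.0382) in the RNAi experiment, a call that was lost when any of several courses or times was left out (adjusted p up to 0.277, without conRNAi course 1). As a group these genes did not move together (camera adjusted p = 0.974 and 0.817).

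**Figure D1:**
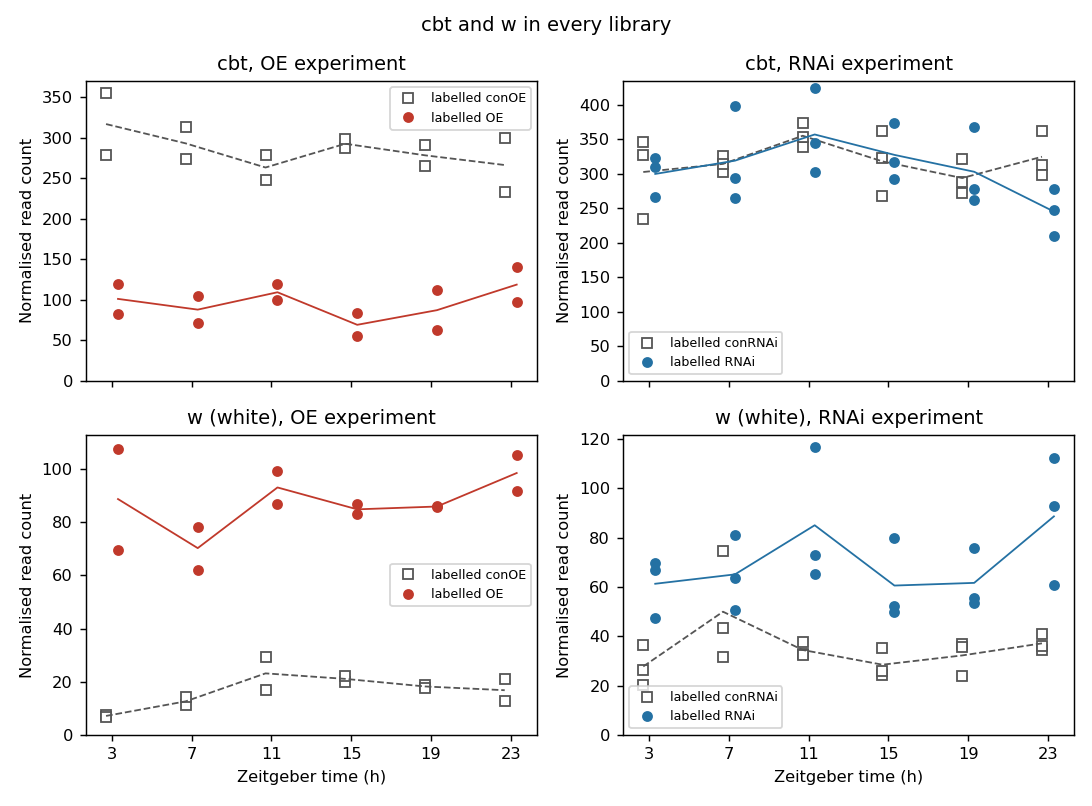
Normalised read counts of cbt (upper panels) and w (lower panels) in every library of the overexpression and RNAi experiments against Zeitgeber time in hours; squares are controls, circles the libraries labelled OE or RNAi, and lines join the means of each time. The cbt counts of the 12 libraries labelled OE lie between 54.74 and 140.3, below all conOE libraries, and those of the libraries labelled RNAi overlap their controls.

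The genotype difference averaged over the day was large in the overexpression experiment. Of 7648 genes tested, 3155 passed limma's test at an adjusted p under 0.05, 1734 of them higher and 1421 lower in the libraries labelled OE, and 454 changed by more than 2-fold (336 higher, 118 lower). The excess of higher genes depended on the deposited scaling: median-ratio rescaling gave 1599 higher and 1618 lower, TMM scaling 1575 and 1643, and edgeR 1725 and 1749. AttA (CG10146), an attacin gene, rose from 17.8 ± 31.8 to 959 ± 353 normalised reads (SD, n = 12 each), a log2 change of 6.52 (SE 0.399, adjusted p = 6.4e-13). The larval serum protein gene Lsp1beta (CG4178) rose from 971 ± 1767 to 36187 ± 12718 (SD, n = 12 each), a log2 change of 6.11, and tobi (CG11909), an alpha-glucosidase gene under the control of insulin-like and glucagon-like signals, by 6.03. The other 7 of the 10 largest increases were CG4757 (6.28), the immune-induced IM18 (6.16), rha (5.67), the cecropin gene CecA1 (5.54), AttB (4.74), the defensin gene Def (4.64) and the antifungal peptide gene Drs (4.53). Adjusted p-values of these 10 genes ran from 1.42e-15 (Def) to 5.92e-12 (CG4757). For genes with few control reads, such as AttA and CecA1 (control mean 8.31), the fold change depends on the pseudocount of 1. The control SD exceeded the control mean for several of these genes, among them AttA, Lsp1beta, CG4757 (69.5 ± 130) and tobi (60.8 ± 103).

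Among the 10 largest decreases, phu (CG8147) fell from 1316 ± 697 to 111 ± 127 normalised reads (SD, n = 12 each), a log2 change of -4.27 (SE 0.487, adjusted p = 7.67e-08). Argl (CG9510), the gene of argininosuccinate lyase, fell from 338 ± 76.4 to 27.9 ± 9.4, a log2 change of -3.59 (SE 0.139, adjusted p = 4.8e-16). The odorant binding protein genes Obp19b (-3.47) and Obp56h (-3.18), the cytochrome P450 gene Cyp6d2 (-3.33), the glucocerebrosidase gene Gba1b (-3.19), Had1 (-2.68), lncRNA:CR32368 (-2.58), CG18783 (-2.47) and CG9498 (-2.44) followed. All 20 genes had the same sign of difference at 6 of 6 times.

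Immune peptide genes rose together. Of 17 measured genes for antimicrobial peptides and peptidoglycan recognition proteins, 17 were higher and 0 lower in the libraries labelled OE, 17 also when adjusted over the list alone, with a median log2 change of 3.14. Limma's camera set test gave adjusted p = 4.89e-20 with its preset correlation and adjusted p = 0.0297 with an estimated correlation. It was the only list of the 26 tested in this experiment to pass both ways. Dso1 rose by 2.58 (adjusted p = 1.42e-15) and BomBc1 by 3.81 (adjusted p = 1.42e-15), beside Def, Drs and the attacins. The mean log2 value over the list lay between 10.591 and 11.807 in the 12 libraries labelled OE and between 7.302 and 8.807 in the 12 conOE libraries. The conOE libraries of course 1 at ZT7 and ZT15 had the highest control values, 8.807 and 8.603, and all others were at 7.691 or below.

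Stress, fat body and digestive enzyme genes were higher in the same libraries. Of 12 measured heat shock and Turandot genes, 8 rose and 1 fell. The humoral stress genes TotC (3.78), TotA (3.31) and TotX (2.30) and the small heat shock protein gene Hsp27 (1.58) rose, and the co-chaperone gene DnaJ-1 fell by 0.52 (camera adjusted p = 0.00478, and adjusted p = 0.267 with an estimated correlation). Of 9 measured genes of the head fat body, the tissue that makes most secreted blood proteins and also antimicrobial peptides, 7 rose and 0 fell, among them Lsp1beta, Lsp2 (2.64), Obp99b (2.53) and GLaz (1.08) (adjusted p = 0.000332, and adjusted p = 0.139 with an estimated correlation). It was 6 of 9 under 2 other scalings. Of 8 amylase and maltase genes 6 rose and 0 fell, led by tobi, Amy-p (4.19) and Amy-d (3.52). Both Amy genes are near-identical copies whose reads could be split between them, so their separate values are uncertain. The list's median of 0.69 lay below its mean of 1.85 (adjusted p = 0.00467, and adjusted p = 0.267 with an estimated correlation). Detoxification genes went both ways, 8 up and 2 down of 12, with Ugt35C1 at 1.17 and Cyp6a2 at -1.75 (adjusted p = 0.0621). Of 20 cuticle protein genes 9 rose and 3 fell, with Cpr72Ec at 2.74 and Cpr11B at -1.07 (adjusted p = 0.182).

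Genes of cytoplasmic ribosomal proteins shifted upward by a small amount. Of 84 measured genes, 68 rose and 0 fell (71 and 0 when adjusted over the list alone), with a median log2 change of 0.38, led by RpL7-like (0.76) and RpS5a (0.71). Under both other scalings 65 rose and 0 fell. The set test gave adjusted p = 2.29e-13 with the preset correlation and adjusted p = 0.358 with an estimated correlation, since these genes vary together between libraries. Mitochondrially encoded transcripts moved the other way, with 0 up and 9 down of 13 and a median of -0.30, ND6 at -0.83 and ND1 at -0.41 (adjusted p = 0.00142, and adjusted p = 0.303 with an estimated correlation).

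Markers of the eye and of neurons were lower in the libraries labelled OE. Of 19 photoreceptor genes 12 fell and 1 rose, with a median of -0.26. The opsin genes Rh4 and Rh3 fell by 0.73 and 0.46 and the scaffold gene inaD rose by 0.34 (camera adjusted p = 0.00187, and adjusted p = 0.197 with an estimated correlation). Of 13 pan-neuronal genes 8 fell and 0 rose, with the synaptotagmin gene Syt1 at -1.38 and Appl at -0.48 (adjusted p = 0.0156, and adjusted p = 0.267 with an estimated correlation). Genes of feeding neuropeptides and receptors followed, 6 down and 1 up of 10, with Dsk at -1.67, Dh31 at -0.82 and the receptor gene sNPF-R at 0.95 (adjusted p = 0.00657, and adjusted p = 0.267 with an estimated correlation). The sNPF-R call was lost without OE course 2 (adjusted p = 0.0581). Of 10 glial genes 6 fell and 2 rose, with Gat at -0.72 and Eaat1 at -0.48 (adjusted p = 0.0621), and under TMM scaling 6 fell and 1 rose. Muscle genes mostly did not pass, 1 up and 2 down of 13 (adjusted p = 0.801). Act87E was at 0.36, and the calls of Mlp60A (-0.39) and Act57B (-0.24) were lost without conOE course 2 (adjusted p = 0.0829) and without conOE course 1 (adjusted p = 0.25). Sex-biased genes of the head included 4 that fell and 1 that rose of 10 (adjusted p = 0.0212, and adjusted p = 0.303 with an estimated correlation). Among them sxe2 fell by 2.15, Cyp4d21 by 1.504 and the sex determination gene dsx by 1.14, and fit rose by 0.96. The sex-biased list joins genes biased to either sex, so its direction as a set has no single reading. The labels give no sex, and a difference in sex composition between the groups was not tested and stays open. Of 3 activity-regulated genes Hr3 (-0.83) and CG14186 (-0.68) fell (adjusted p = 0.068).

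Metabolic genes moved in both directions. Of 11 genes of gluconeogenesis, glyceroneogenesis and cataplerosis, 6 fell and 3 rose (camera adjusted p = 0.0869). The glycerol-3-phosphate dehydrogenase gene Gpdh1 fell by 1.92, the phosphoenolpyruvate carboxykinase gene Pepck1 by 1.40, the glycerol kinase gene Gk1 by 1.22 and the pyruvate carboxylase gene PCB by 1.03, while the aspartate aminotransferase gene Got2 rose by 1.53. Lipid synthesis and storage included 6 that fell and 2 that rose of 10 (adjusted p = 0.0497, and adjusted p = 0.303 with an estimated correlation). The perilipin gene Lsd-1 fell by 2.05, AcCoAS by 1.38 and Men by 0.85, and the fatty acid synthase gene FASN1 rose by 0.76. Of 12 lipolysis genes 4 rose and 4 fell, with the lipase gene bmm at 0.97 and yip2 at -0.95 (adjusted p = 0.932). Glycolysis had 5 up and 4 down of 13, with Ldh at 1.13 and Hex-C at -1.79 (adjusted p = 0.743), and 3 up and 4 down under 2 other scalings. Of 7 pentose phosphate genes Rpi passed at 0.34, a call lost without conOE course 1 (adjusted p = 0.166), and Zw was at -0.28 (adjusted p = 0.0564), which passed under TMM scaling at -0.32 (adjusted p = 0.0253); the list did not pass (adjusted p = 0.932). Insulin and adipokinetic hormone genes had 4 up and 5 down of 11 (adjusted p = 0.793), with the insulin antagonist gene ImpL2 at 1.27, Ilp5 at 0.91 and the hormone receptor gene AkhR at -1.15. Of 8 sugar sensing genes 4 rose and 2 fell (adjusted p = 0.974), with the sugar transporter gene Tret1-1 at 0.75 beside cbt. The activin ligand gene daw (-0.72) and hep (-0.56) were among 4 of 13 genes of the activin and JNK pathways that fell, with 0 up (adjusted p = 0.328). Of the gut serine proteases only Jon44E was measured in the overexpression table and 0 in the RNAi table. Its log2 change of -0.35 (adjusted p = 0.328) passed without conOE course 2 (-0.81, adjusted p = 0.0267), and turned to 0.11 without conOE course 1 and to 0.04 without OE course 1.

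Several clock genes changed their daily mean in the libraries labelled OE, in both directions. The period and timeless genes, whose proteins repress the clock's own transcription, rose: per from 51.8 ± 37 to 75.5 ± 46 (SD, n = 12 each, over all times), a log2 change of 0.68 (SE 0.141, adjusted p = 0.000348), and tim from 444 ± 331 to 760 ± 500, a log2 change of 0.93 (SE 0.0912, adjusted p = 5.24e-09). The circadian neuropeptide gene Pdf fell by 1.24 (adjusted p = 3.51e-11), the repressor gene cwo by 0.87 (adjusted p = 1.46e-05) and the blue light receptor gene cry by 0.63 (adjusted p = 3.05e-05), while the receptor gene Pdfr rose by 0.63. cyc rose by 0.38 (adjusted p = 0.00438), a call that was lost without conOE course 1 (adjusted p = 0.0628). Clk (0.18, adjusted p = 0.348), vri (0.07, adjusted p = 0.72) and Pdp1 (-0.003, adjusted p = 0.982) did not pass. As a list the 14 core clock and kinase genes had 4 up and 3 down (camera adjusted p = 0.974), and 10 clock output genes 3 up and 3 down (adjusted p = 0.974), with MFS14 at -1.99 and Cyp18a1 at 0.98.

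The 3155 calls rest on libraries of 2 courses per genotype. With 1 value per course, a comparison of 2 against 2, 1986 genes passed, 1980 of them among the 3155. The counts of list members adjusted over the list alone differed from those over all genes in 5 of the 26 lists tested: ribosomal proteins (71 up, 0 down), mitochondrially encoded (0 up, 10 down), feeding (1 up, 7 down), sex-biased (2 up, 4 down) and lipid synthesis (3 up, 6 down). The median, mean and test of a list differed in sign, by small amounts, for clock output, sugar sensing, pentose phosphate and lipolysis genes.

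**Figure D2:**
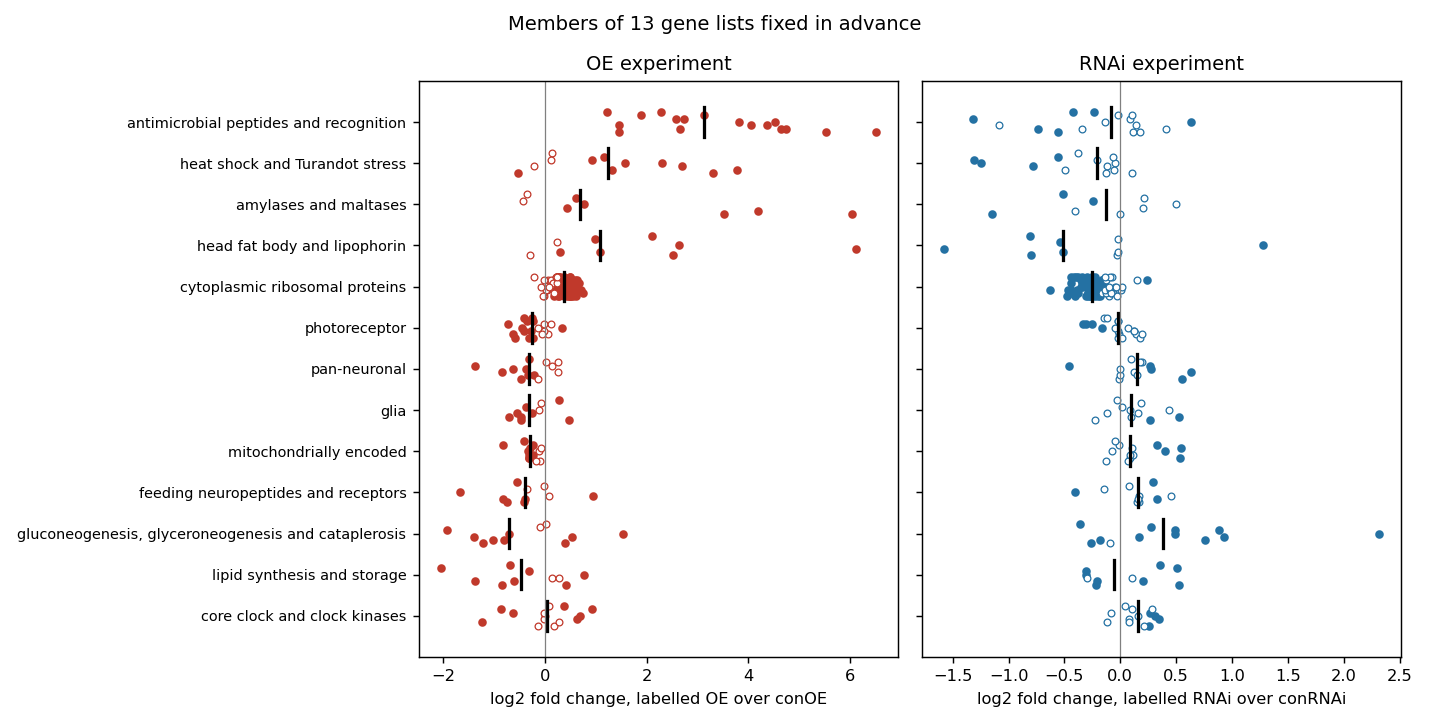
Log2 fold changes of the members of 13 gene lists in the libraries labelled OE over conOE (left) and labelled RNAi over conRNAi (right); each point is a gene, filled where its adjusted p is under 0.05, and black bars are medians. All 17 antimicrobial genes lie above 0 on the left, and ribosomal protein genes lie mostly above 0 on the left (median 0.38) and below 0 on the right (median -0.25).

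Whether the genotype difference depended on the time of day was asked with a test of the genotype-by-time terms. No gene of 7648 passed limma's test in the overexpression experiment, with 121 at an unadjusted p under 0.05. On the recovered reads edgeR called 0 genes, with 120 at an unadjusted p under 0.05. The 5 genes of lowest p were CG8654, CG10513, Def, CG11891 and CG4842, each at an adjusted p of 1. Some genes passed without conOE course 2, Def among them, and without OE course 1, CG8654 among them. Those fits left 1 library per time in the genotype that lost a course. The spread then came from the other genotype alone, so these calls cannot show a dependence on time. In simulated data of this size, with each change placed at ZT11, the test recovered 57.3% of 4-fold changes confined to 1 time and 4% of 2-fold ones. Most 2-fold changes at single times would thus be missed at this depth and replication. The simulated libraries had no course differences, and ZT23 held shallower libraries (lowest 468075 reads), so recovery at other times may be lower. The 121 genes of 7648 are also below the share of 0.05 that chance gives, so the test was conservative here.

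Daily rhythms were present in both genotypes of the overexpression experiment. A 24 h harmonic was called in 92 genes in the conOE libraries and 46 in the libraries labelled OE, 29 in both. The test of the difference in rhythm itself called 0 of 7648 genes, with 312 at an unadjusted p under 0.05, so the 2 counts do not show a loss of rhythm. On the recovered reads edgeR called 107 and 78 rhythmic genes, and 1 gene, CG10513, with a rhythm difference (edgeR adjusted p = 0.0327; 294 genes at an unadjusted p under 0.05). Under limma CG10513 stood at an adjusted p of 0.19, as did CG4842 and CG11891, and MFS9 and CG16772 at 0.959 and 0.999. With the course as a block within the genotype 107 and 71 genes were rhythmic. Lost amplitudes of 0.5 were recovered for 6% of simulated genes by the difference test and those of 1 for 68%. tim cycled with a log2 amplitude of 1.97 and a peak at ZT15.6 in the conOE libraries and 1.65 and ZT15.9 in the libraries labelled OE (adjusted p of the difference 0.999). vri had amplitudes of 1.79 and 1.92 with peaks at ZT13.4 and ZT13, per amplitudes of 1.62 and 1.26 with peaks at ZT13.6 and ZT14.3, and Clk, in the opposite phase, amplitudes of 0.97 and 0.93 with peaks at ZT2.04 and ZT1.42. cry had amplitudes of 0.56 and 0.60 (adjusted p = 0.0482 and 0.0574), and Pdp1 did not pass in either group (adjusted p = 0.0536 and 0.125), nor did cwo (adjusted p = 0.375 and 0.337) and cyc (adjusted p = 0.909 and 0.847). cbt had no rhythm in either group (adjusted p = 0.929 and 0.798). These counts depend on the courses. With 1 course left, 13 and 7 genes were called in the conOE libraries (without conOE course 1 and course 2) and 117 and 109 in the libraries labelled OE (without OE course 1 and course 2). A rhythm difference was called for 1 gene without conOE course 1 and for 2 without OE course 1. In the authors' deposited table, whose rhythm test differs, 576 genes in the controls and 536 in the libraries labelled OE stood at a q under 0.05, 123 in both.

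**Figure D3:**
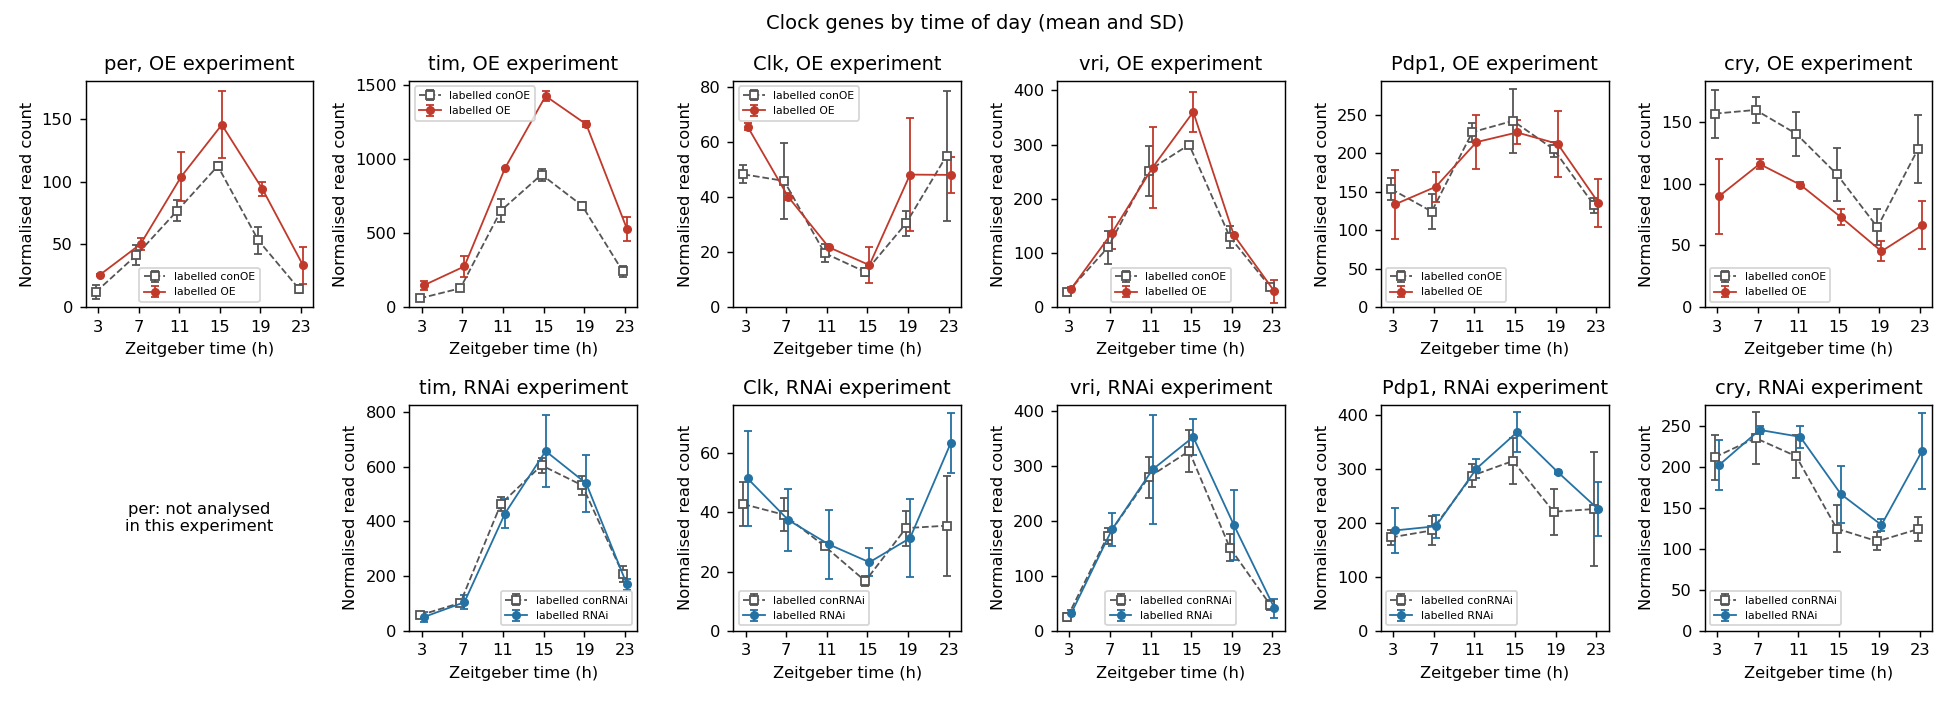
Normalised read counts of per, tim, Clk, vri, Pdp1 and cry against Zeitgeber time in hours in the overexpression experiment (upper panels, 2 libraries per point) and, without per, in the RNAi experiment (lower panels, 3 libraries per point); points are means, bars SDs, squares controls and circles the libraries labelled OE or RNAi. tim peaks near ZT15 in all 4 groups, and its level is higher in the libraries labelled OE at 6 of 6 times.

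The genotype difference of the RNAi experiment was smaller. Of 7444 genes, 1664 passed limma's test, 687 higher and 977 lower in the libraries labelled RNAi, and 78 changed by more than 2-fold (34 higher, 44 lower). The excess of lower genes was smaller under other scalings and by edgeR, with 751 higher and 927 lower by median-ratio rescaling, 738 and 937 by TMM scaling and 915 and 998 by edgeR. The cytochrome P450 gene Cyp4e3 (CG4105) rose from 48.9 ± 20.4 to 1915 ± 478 normalised reads (SD, n = 18 each), a log2 change of 5.30 (SE 0.129, adjusted p = 1.91e-31). CG3348 rose by 3.14 (SE 0.0968, adjusted p = 1.44e-27), and Pepck2, a second phosphoenolpyruvate carboxykinase gene, from 7.45 ± 6.4 to 34.0 ± 11.7 (SD, n = 18 each), a log2 change of 2.32 (SE 0.217, adjusted p = 2.04e-11). The next 7 were Cyp6a8 (2.23), CG3609 (2.03), CG8654 (1.78), the aldo-keto reductase gene Akr1B (1.71), CG5966 (1.67), CG33958 (1.61) and CG9377 (1.61). Cpr72Ec, a cuticle protein gene, had the largest decrease, from 1002 ± 746 to 143 ± 74.3 (SD, n = 18 each), a log2 change of -2.60 (SE 0.163, adjusted p = 1.21e-16). CG18249 (-2.46), the inositol phosphate kinase gene Ipk1 (-2.22), lncRNA:CR32368 (-2.07), CG16743 (-2.03), CG3513 (-1.71), the cathepsin gene CtsL3 (-1.68), Lsp1beta (-1.58), CG8157 (-1.47) and CG11842 (-1.34) followed. All 20 had the same sign at 6 of 6 times. The number called fell to 1067 without conRNAi course 1 and to 672 with 1 value per course (3 against 3), 665 of them among the 1664.

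Ribosomal protein genes were lower in the libraries labelled RNAi. Of 84 measured, 64 fell and 1 rose (68 and 1 when adjusted over the list alone), with a median of -0.25, led by RpL11 (-0.63) and RpL22 (-0.44), and 63 fell under both other scalings. The set test gave adjusted p = 4.41e-20 with the preset correlation and adjusted p = 0.394 with an estimated correlation. Of 13 mitochondrially encoded transcripts 4 rose and 0 fell, ND5 by 0.54 and ND3 by 0.53 (adjusted p = 0.0326, and adjusted p = 0.394 with an estimated correlation). None of the 26 lists tested in this experiment passed with an estimated correlation, the lowest adjusted p being 0.214.

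Metabolic genes that had been lower in the libraries labelled OE included several that rose here. Of 12 genes of gluconeogenesis, glyceroneogenesis and cataplerosis 8 rose and 3 fell (camera adjusted p = 0.00362, and adjusted p = 0.38 with an estimated correlation). Pepck2 led, a gene not measured in the overexpression experiment. Pepck1 (0.93) and Gpdh1 (0.89), which were lower in the libraries labelled OE, rose, as did the glycerol kinase gene Gk2 (0.76). Of 7 pentose phosphate genes 3 rose and 0 fell: the transketolase gene CG8036 (0.40), the glucose-6-phosphate dehydrogenase gene Zw (0.39) and Taldo (0.29) (adjusted p = 0.0356, and adjusted p = 0.394 with an estimated correlation). The Taldo call was lost with 1 value per course (adjusted p = 0.0645). Lipid synthesis genes split into 4 up and 4 down of 10, with Lsd-1 at 0.51 and Men at 0.52 (adjusted p = 0.71), and lipolysis genes into 3 and 3 of 12, with whd at 0.44 beside CG5966 (adjusted p = 0.901). Glycolysis had 4 up and 1 down of 13, with Hex-A at 0.45 and Hex-C at -0.60 (adjusted p = 0.925). Of 8 sugar sensing genes Tret1-1 (0.40) and daw (0.42) rose and 0 fell (adjusted p = 0.242). Of 10 insulin and adipokinetic hormone genes 3 rose and 1 fell, ImpL2 by 0.78 and Ilp5 by 0.72 upward and AkhR by 0.35 downward (adjusted p = 0.0565). The AkhR call was lost without conRNAi course 1 (adjusted p = 0.0621) and without ZT15 (adjusted p = 0.0831). Detoxification genes had 3 up and 4 down of 10, with Cyp6w1 at 0.61 beside Cyp6a8 (adjusted p = 0.578).

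Genes of the fat body and cuticle included more that fell than rose. Of 9 head fat body genes 5 fell and 1 rose, with Lsp1beta, the apolipophorin gene apolpp (-0.51) and the lipid transfer gene Mtp (-0.54) lower and Lsp2 higher (1.28) (camera adjusted p = 0.0356, and adjusted p = 0.394 with an estimated correlation). Of 17 cuticle protein genes 8 fell and 1 rose, Cpr65Au at 0.55 (adjusted p = 0.0233, and adjusted p = 0.214 with an estimated correlation), and 2 other scalings gave 2 up, with 7 and 8 down. Of 16 antimicrobial genes 5 fell and 1 rose (adjusted p = 0.242). PGRP-SD fell by 0.74, PGRP-SB1 by 0.56 and Mtk by 1.32, and BomBc1 rose by 0.63. Except for PGRP-SD these calls were lost on leaving out a course or time: PGRP-SB1 and Mtk without conRNAi course 1 (adjusted p = 0.0752 and 0.132), Mtk also without ZT11, ZT15 or ZT19 (adjusted p up to 0.143), and BomBc1 without conRNAi course 2 or ZT23 (adjusted p = 0.062 and 0.0789). Of 13 heat shock and Turandot genes 4 fell and 0 rose (adjusted p = 0.105), TotM by 1.31 and TotA by 0.78, both lost without RNAi course 2 (adjusted p = 0.107 and 0.0897), and TotA also without ZT15 (adjusted p = 0.0521). Of 8 amylase and maltase genes 3 fell and 0 rose, Mal-B2 by 0.51 and tobi by 1.15 (adjusted p = 0.242).

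Cell type markers moved little in the RNAi experiment. Of 19 photoreceptor genes 4 fell and 0 rose, Rh4 by 0.31 and trpl by 0.25 (camera adjusted p = 0.709), and the trpl call was lost without conRNAi course 3 (adjusted p = 0.0833) or RNAi course 2 (adjusted p = 0.0517). Of 13 pan-neuronal genes 4 rose and 1 fell, the active zone gene brp by 0.55 upward (with 1 value per course adjusted p = 0.0575) and Syt1 by 0.46 downward (adjusted p = 0.149). Of 11 glial genes nrv2 (0.53) and Eaat1 (0.27) rose and 0 fell (adjusted p = 0.105). In the muscle list 1 of 13 passed, Mlc2 at 0.32, which was lost on leaving out any of 4 courses or 3 times (adjusted p up to 0.148), and Mhc at 0.14 did not pass (adjusted p = 0.191) except without RNAi course 3 (0.28, adjusted p = 0.00558); the list's adjusted p was 0.201. Of 10 feeding neuropeptide genes 2 rose and 1 fell, with Dsk at -0.40 and Dh31 at 0.32 (adjusted p = 0.242), and the Dh31 call was lost on leaving out any of 3 courses or 3 times (adjusted p up to 0.0873). Of 9 sex-biased genes 4 fell and 0 rose (adjusted p = 0.264). The calls of Yp3 (-0.64) and fit (-0.82) were lost without RNAi course 3 (adjusted p = 0.135 and 0.214), and that of fit also without conRNAi course 2 (adjusted p = 0.164). In the activin and JNK list daw alone passed, 1 of 12 (adjusted p = 0.787), and kay was at -0.20 (adjusted p = 0.0898) but passed without conRNAi course 2 (-0.31, adjusted p = 0.0134), without RNAi course 2 (-0.27, adjusted p = 0.049), under edgeR, and without the libraries of low depth. Of 3 activity-regulated genes 0 passed (adjusted p = 0.914). The counts adjusted over the list alone differed for glycolysis (4 up, 2 down), lipid synthesis (4 up, 5 down), lipolysis (3 up, 4 down), insulin (4 up, 1 down), muscle (0 and 0), cuticle (2 up, 8 down), antimicrobial (1 up, 6 down), mitochondrially encoded (4 up, 1 down), ribosomal and core clock genes. The median, mean and test of a list differed in sign for glycolysis, lipid synthesis, lipolysis, detoxification, activin and JNK, and construct genes.

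Clock genes were little changed in the libraries labelled RNAi. Of 13 measured core clock and kinase genes 4 rose and 0 fell (camera adjusted p = 0.0492, and adjusted p = 0.214 with an estimated correlation), 5 and 0 when adjusted over the list alone. The kinase genes sgg (0.32; with 1 value per course adjusted p = 0.0888), dco (0.26) and nmo (0.35) and cry (0.27, SE 0.0792, adjusted p = 0.00972) passed. cry lost its call without conRNAi course 3 (adjusted p = 0.128), RNAi course 2 (adjusted p = 0.0673) or ZT23 (adjusted p = 0.111), dco without conRNAi course 1 (adjusted p = 0.0774), and nmo without conRNAi course 1 (adjusted p = 0.141), RNAi course 3 (adjusted p = 0.0867), ZT19 or ZT3. tim (-0.08, adjusted p = 0.489), Clk (0.21, adjusted p = 0.308), cyc (0.04, adjusted p = 0.874), vri (0.11, adjusted p = 0.515), Pdp1 (0.16, adjusted p = 0.172) and cwo (0.29, adjusted p = 0.0531) did not pass, and per was not analysed in this experiment. cwo passed in 9 alternatives, among them TMM scaling (0.30, adjusted p = 0.048) and 2 left-out courses; vri passed without RNAi course 3 (0.26, adjusted p = 0.0256), and Pdp1 without RNAi course 3 (0.23, adjusted p = 0.0449) or conRNAi course 2 (0.29, adjusted p = 0.00365). Of 10 clock output genes 3 rose and 1 fell, with MFS14 at 0.67 and Ugt35B1 at 0.38 (adjusted p = 0.242).

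No gene of 7444 showed a genotype difference that depended on the time of day in the RNAi experiment by limma, with 336 at an unadjusted p under 0.05, nor by edgeR, with 223. The 5 genes of lowest p were spn-F, CG1116, Hmu, Mtk and CaBP1, each at an adjusted p of 0.834. Without RNAi course 1, 11 genes passed, among them CG1116 (adjusted p = 0.0394), Mtk (adjusted p = 0.00731) and CaBP1 (adjusted p = 0.0338). A 24 h harmonic was called in 305 genes in the conRNAi libraries and 162 in the libraries labelled RNAi, 107 in both, and 0 genes differed in rhythm by limma (313 at an unadjusted p under 0.05) or by edgeR (290). Tret1-1, Gp93, whd and Atac3 came nearest (adjusted p = 0.675), then Cbl (0.903). tim cycled with amplitudes of 1.76 and 1.88 and peaks at ZT15.8 and ZT15.6, and vri with amplitudes of 1.81 and 1.81 and peaks at ZT13.3 and ZT13.2. The rhythmic counts fell to 135 and 149 in the conRNAi libraries without course 1 and course 3, and to 71 and 62 in the libraries labelled RNAi without course 1 and course 3. A q under 0.05 was given in the authors' deposited table to 939 genes in the controls and 821 in the libraries labelled RNAi, 315 in both. Simulated amplitudes of 1 lost in 1 genotype were recovered for 89% of genes, and amplitudes of 0.5 for 40%.

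The 2 genotype effects moved many genes in opposite directions. Of 6987 genes tested in both, 457 were higher in the libraries labelled OE and lower in those labelled RNAi, against 220.2 for independent lists (odds ratio 3.86, Fisher's exact test, 2-sided p = 1.51e-74). A further 200 were lower in the libraries labelled OE and higher in those labelled RNAi, against 126.4 (odds ratio 1.99, exact p = 4.03e-13). Together 657 genes moved oppositely, against 346.7 for independent lists. Genes higher in both were fewer than independent lists give, 118 against 146.6 (odds ratio 0.742, exact p = 0.00487), and genes lower in both numbered 169 against 189.9 (odds ratio 0.848, exact p = 0.0737). These 4 tests form 1 family, genes are not independent replicates, and the experiments share no control libraries. Across genes, the log2 changes had a Pearson r of -0.171 and a Spearman rho of -0.194. With 1 value per course 233 genes moved oppositely and 111 in the same direction.

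Genes that were higher in the libraries labelled OE and lower in those labelled RNAi were led by CG11841 (1.72 and -1.05), Drsl5, a drosomycin-like gene (2.57 and -0.86), Cpr72Ec (2.74 and -2.60), CG15293 (1.78 and -0.59) and the immune peptide gene BomT2 (2.13 and -0.90). The reverse class was led by Gpdh1 (-1.92 and 0.89), CG32444 (-2.16 and 1.09), MFS14 (-1.99 and 0.67), CG10214 (-2.03 and 0.56) and Lsd-1 (-2.05 and 0.51). The glutathione transferase gene GstE3 (1.67 and 1.10), Cyp4p1 (2.58 and 1.21), ImpL2 (1.27 and 0.78), w (2.42 and 0.996) and CG13067 (1.333 and 0.98) rose in both. Obp49a (-1.59 and -1.18), CG9498 (-2.44 and -0.99), CG16743 (-1.59 and -2.03), the eye pigment transporter gene bw (-1.91 and -0.96) and Cyp6a20 (-0.93 and -0.72) fell in both. All 20 passed in both experiments, at adjusted p-values of at most 1.07e-08 (CG13067 in the overexpression experiment).

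**Figure D4:**
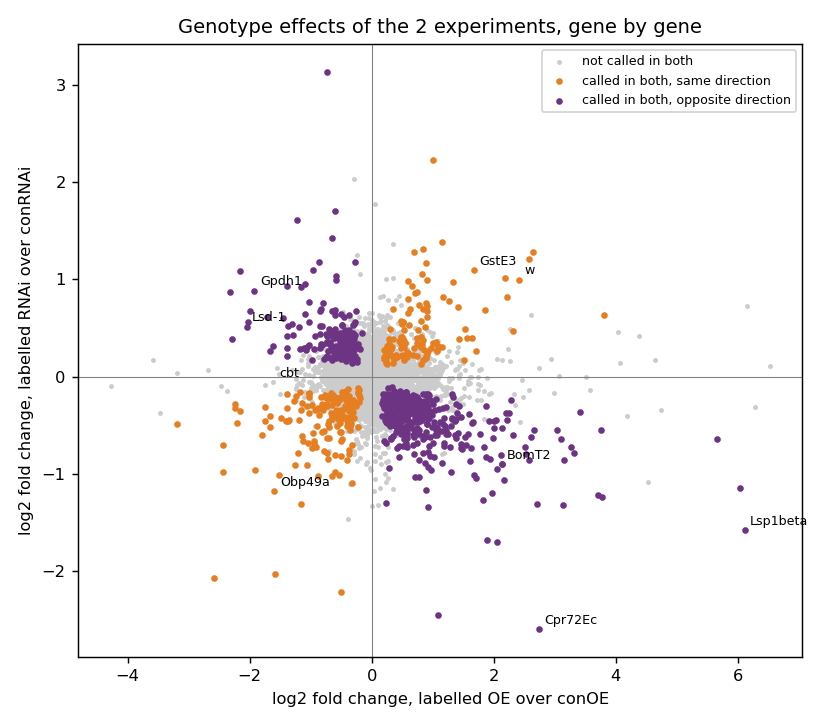
Log2 fold changes of 6987 genes in the libraries labelled OE over conOE (horizontal axis) and in the libraries labelled RNAi over conRNAi (vertical axis); each point is a gene, coloured by whether it passed in both experiments and in which directions. The 657 genes that passed in both with opposite signs outnumber the 287 with the same sign.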

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

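The tests with edgeR, TMM scaling, the crossed block, all distinct transcripts and without libraries under 1000000 reads were chosen after the results were seen. Of 125 named genes, 2720 genotype values under the alternatives kept direction and side of the threshold in the overexpression experiment, 11 fell below it, 11 passed it newly and 8 turned sign. For 105 genes of the RNAi experiment these were 2319, 70, 19 and 7. The cause was not tested, except that fewer samples remain where a course, a time or libraries were left out and where 1 value per course was used.

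With 1 value per course 1986 genes passed in the overexpression experiment and 672 in the RNAi experiment, 233 of them moving oppositely and 111 in the same direction in both. With courses left out the overexpression genotype effect called 2204 to 2813 genes and the RNAi effect 1067 (without conRNAi course 1) to 1899. The interactions called 0 to 14 (without OE course 1) and 0 to 11 (without RNAi course 1), and the overexpression rhythm difference 0 to 2. Rhythmic genes ranged from 7 to 13 in conOE, 109 to 117 in OE, 135 to 287 in conRNAi and 62 to 108 in RNAi. On recovered reads edgeR called 78 rhythmic genes in OE and 1 overexpression rhythm difference. Opposite changes ranged from 438 to 780 and same-direction changes from 216 to 272. The log2 change of cbt ranged from -1.693 to -1.526 in the overexpression experiment and from -0.1 to 0.01 in the RNAi experiment. With the course as a random block, the correlation within a course was 0.0242 in the overexpression experiment and 0.0863 in the RNAi experiment. Mlc2, v, nmo and Mtk then lost their calls in the RNAi experiment (limma adjusted p = 0.0791, 0.125, 0.0606 and 0.0502).

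The replicate numbers were not taken to pair the courses, since the labels give no pairing and not every pair correlated. Deviations of same-numbered courses had correlations of -0.212 in the overexpression experiment and 0.00328, 0.25 and 0.322 in the RNAi experiment. Course 1 had its fewest reads at ZT19 and course 2 at ZT23 in each of the 4 genotypes, while course 3 had them at ZT19 in conRNAi and ZT23 in RNAi, so batches shared by courses 1 and 2 stay open. With the replicate block 3158 and 1821 genes passed, 71 genes were rhythmic in OE, 107 in conOE, 445 in conRNAi and 236 in RNAi, and 0 genes passed the interactions and rhythm differences. The negative correlation is that of course means; taken per time it averaged 0.0114 (-0.263 to 0.195), so crossed numbers are not shown. With the crossed block 3257 genes passed the overexpression genotype effect, 0 the interaction and 1 the rhythm difference.

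Signs turned only for values under the threshold. In the overexpression experiment, with courses left out, vri ranged from -0.003 to 0.147, Pdp1 from -0.091 to 0.084 and Jon44E from -0.813 to 0.11, with 0.008 for Pdp1 without OE course 2 and 0.037 for Jon44E without OE course 1. Pdp1 was at 0.043, 0.015 and 0.013 without ZT3, ZT11 and ZT15. In the RNAi experiment cbt was at 0.015 without ZT23, tim ranged from -0.201 to 0.016 and cyc from -0.151 to 0.193, with -0.126 without RNAi course 3. cyc was at -0.008 without ZT15, -0.066 without ZT23, -0.008 under edgeR and -0.098 without libraries under 1000000 reads.

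Other scalings, pseudocounts and filters left the counts of genes called over all genes, in each test, within 1.5 times their values; the lack of a filter changed nothing, since the planned one removed no gene. Without libraries under 1000000 reads 3320 and 1890 genes passed. All distinct transcripts gave 3462 and 1829. Simulated rhythm differences with an amplitude of 0.5 were recovered for 6% of genes in the overexpression experiment.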

Other observations

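The tests of the name families, of swapped labels, exchanged fly lines and the transgene's 3′ end, and of a deviant course, more fat body and microbial load were chosen after the results were seen. Families of genes sharing a name stem were tested with camera, 85 families in each experiment. In the libraries labelled OE the glucuronosyltransferase family Ugt had 10 genes up and 1 down of 13 (median 0.74, adjusted p = 0.000864, and adjusted p = 0.367 with an estimated correlation), with Ugt36F1 at 1.79. Serpin genes (Spn) had 9 up and 0 down of 11 (adjusted p = 0.00276, and adjusted p = 0.668 with an estimated correlation), with Spn28Dc at 1.92. Of the proteasome subunit families, 6 of 8 Prosalpha genes rose (adjusted p = 0.00627, and adjusted p = 0.509 with an estimated correlation). So did 7 of 7 Prosbeta genes (adjusted p = 0.0234, and adjusted p = 0.595 with an estimated correlation). Prosalpha1R (1.09) and Prosalpha1 (1.07) rose most, and the others by smaller amounts, with Prosbeta2 at 0.44. The Rpn and Rpt families did not pass, with 5 of 12 and 2 of 6 genes up (adjusted p = 0.32 and 0.672). Of 8 immune peptide genes named BomS or BomT, some of which are also in the antimicrobial list, 7 rose and BomS4 fell by 0.50 (adjusted p = 5.71e-06, and adjusted p = 0.367 with an estimated correlation). Neprilysin-like genes (Nepl) had 12 up and 4 down of 16 (adjusted p = 0.0478, and adjusted p = 0.705 with an estimated correlation), with Nepl18 at 1.99 and Nepl11 at -1.06, and cathepsin genes (Cts) 4 up and 0 down of 6 (adjusted p = 0.00445, and adjusted p = 0.367 with an estimated correlation), with CtsL3 at 1.90 and CtsK1 at 1.55. PGRP (6 up, 0 down of 8, adjusted p = 0.00445) and Rh genes (0 up, 5 down of 7, adjusted p = 0.0216), which overlap the fixed lists, also passed, at adjusted p = 0.367 each with an estimated correlation. The medians of these families kept their sign under both other scalings.

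In the libraries labelled RNAi all 6 measured imaginal disc growth factor genes (Idgf) fell, with a median of -0.59 (adjusted p = 2.39e-07, and adjusted p = 0.00395 with an estimated correlation). Idgf6 fell by 0.65 and Idgf1 by 0.28, and the call of Idgf1 was lost without conRNAi course 1 (adjusted p = 0.0827) or ZT11 (adjusted p = 0.0763). Odorant binding protein genes (Obp) had 11 down and 1 up of 19 (adjusted p = 0.000102, and adjusted p = 0.0951 with an estimated correlation), with Obp49a at -1.18, Obp56d at -0.72 and Obp44a at 0.54. Neprilysin-like genes (Nepl) had 9 down and 1 up of 15 (adjusted p = 0.00294, and adjusted p = 0.368 with an estimated correlation), with Nepl12 at -1.27 and Nepl4 at 0.57. Serpin genes had 7 down and 0 up of 12 (adjusted p = 0.0138, and adjusted p = 0.568 with an estimated correlation), with Spn88Eb at -1.01. BomS and BomT genes had 6 down and 0 up of 8 (median -0.38, adjusted p = 0.00292, and adjusted p = 0.435 with an estimated correlation), and cathepsin genes 3 down and 0 up of 6 (adjusted p = 0.00596, and adjusted p = 0.19 with an estimated correlation), with CtsL3 at -1.68 and CtsK2 at -0.86. Cpr cuticle genes, which overlap a fixed list, had 8 down and 1 up of 16 (adjusted p = 0.0138, and adjusted p = 0.368 with an estimated correlation). The medians kept their sign under both other scalings.

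For both genotype effects, chance assignment of single libraries within each time was excluded by 100 splits, which treat libraries of a course as exchangeable: 1 of 100, the real one, gave as many genes, with 3155 against at most 1410 in the others for the overexpression experiment and 1664 against at most 752 for the RNAi experiment. Whole courses give only 3 and 10 splits, too few for a share under 0.05; the real ones called 3155 and 1664 genes and the highest others 1 and 1025, the latter joining conRNAi courses 1 and 3 with RNAi course 3, so that differences between whole courses stay open. For rhythmic genes 1 of 100 draws of the time labels, the real one, gave as many in each genotype, 92 against 14 in conOE, 46 against 9 in OE, 305 against 10 in conRNAi and 162 against 5 in RNAi. The splits decide nothing about the overlaps of the experiments: nearly all other splits called 0 genes, so the highest overlap of the others was 0 whatever the real ones (657 opposite and 287 in the same direction, 1 of 100 pairs of splits each), and 287 lies below the 336.5 of independent lists. With 0 genes called, any split gives as many, so the 100 of 100 splits for each interaction and rhythm difference decide nothing. Other splits called up to 949 and 1918 genes in the overexpression experiment and 98 and 1 in the RNAi experiment; they put libraries of 1 genotype on different sides at different times, which points to the genotype structure of the samples.

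cbt was lower in the libraries labelled OE, against the label. A swap of the labels conOE and OE is not settled by distances between groups. Over all other genes the driver control of the RNAi experiment lay nearer to conOE than to OE at 6 of 6 times, with a highest distance ratio of 0.663. The tables were normalised separately, but conOE and OE stand in 1 table, so both distances share that offset. The libraries labelled RNAi, whose label gives a UAS construct, also lay nearer to conOE at each time, such as 0.4588 against 0.7666 at ZT3. The distances thus show that the libraries labelled OE stood apart, and not which label is right. The marker gene w lay at 62.21 to 107.8 in the 12 libraries labelled OE and at 6.57 to 29.47 in the 12 conOE libraries. If the UAS-cbtFLAG insertion carries w and the genotypes do not otherwise differ at w, these values argue against a swap. Neither condition was tested here. An exchange of fly lines between the experiments stays open, since Dcr-2 differed by only -0.393 log2 between the controls across separately normalised tables. Within the RNAi experiment Dcr-2 did not pass either, although only the conRNAi label lists UAS-Dcr2. Transgene transcripts ending outside the counted 3′ end also stay open, since only 1 cbt transcript (-1.61) is listed and the construct's sequence was not used here.

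Immune peptide genes were higher in the libraries labelled OE. A single deviant course is argued against by the lowest of 4 median differences between courses, 2.89, and an infection that came and went between libraries by the 12 of 12 libraries labelled OE above every control library. More fat body in the heads stays open: the fat body list rose, and the lipid synthesis list moved down (limma's directional rotation test, n = 12 each, p = 1.27e-06) but went both ways and did not pass with an estimated correlation (adjusted p = 0.303). A lasting infection of the stock, a difference in genetic background and an effect of the transgene could each give this pattern, and the design does not separate them.

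The experiments moved genes in opposite directions. A trend with expression level is argued against by a correlation across genes of -0.155 after its removal. Linkage of the opposite genes to 1 chromosome arm is argued against by the ratio to its share farthest from 1, 1.18 (2L). In the RNAi experiment 28.4% of genes on 2L and 26.7% on 2R were called, against 17.6% (3L), 20.1% (3R) and 19.2% (X). In the overexpression experiment the shares on these arms ran from 36% (X) to 44.2% (2R). A link to a whole chromosome was not tested and stays open. The listed ribosomal and antimicrobial genes as the sole source are argued against by a ratio to independent lists of 1.84 without both lists. Immune genes outside the list, such as Drsl5, stayed in, so a wider immune response stays open. Opposite effects of the 2 constructs could give this pattern, as a hypothesis. The cbt row did not move oppositely (-1.61 and -0.06), but it may not count the transgene's transcripts and so does not decide this. Differences in genetic background stay open.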
